A study of Homo sapiens with 2 samples.

How the data were processed

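Total RNA from 2 cultures of Huh7 cells was labelled with Cy3 and hybridised to 1 array each, on the same slide. The arrays carry probes of 60 bases. One sample was grouped as THADA knockdown and the other as control, from the treatment characteristic in the labels.

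The deposited scanner files hold spot intensity values. Per the file headers, they were made with Agilent Feature Extraction 10.7.1.1, which subtracted background and corrected spatial trends within each array. The submitters' processing notes name version 9.5.1.1, and which version holds for the other table is not given in the sources used here. The table of processed values deposited by the authors holds 1 signal per probe on a linear scale. Its columns hold the same sorted values, so it was quantile normalized, and it was used only as an alternative. Probe coordinates are those of the files (hg19). No column of per-sample values was left unmapped.

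The processed intensity of each spot was turned into log2, and each array's 75th percentile over spots for human transcripts was subtracted. This assumes that most of the upper range of signals is alike on both arrays. Control spots and outlier spots were left out (290 spots on the knockdown array and 242 on the control array). Spots of one probe were averaged, which gave 50599 probes, 902 of them spotted 10 times. Of these probes, 20828 were well above background on both arrays, 926 on the knockdown array only and 3240 on the control array only. Probes were named through RefSeq gene names (assembly GRCh38, used for names only). By accession 28174 probes matched, by symbol 2618 and by an older symbol 620. The other 19187 kept the name in the file. A gene was represented by its brightest probe among those well above background on both arrays, which gave 16000 genes, 13304 of them with a RefSeq symbol. Of 937 genes at least 2-fold different with more than 1 measured probe, all probes went the same way in 876 (93.5%). A gene well above background on only 1 array has a bound. The bright signal was set against the higher of the dim probe's own signal and the lowest signal well above background on that array, and the ratio is written as "at least".

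With 1 array per group no test was made. Differences of at least 2-fold were counted. Each gene list's median was set against 10000 random lists of the same size, matched on mean signal in 20 bins, as a description of these arrays. Technical error came from repeated spots and from Agilent's error model (median 0.206 in log2 for a single spot), and neither includes differences between cultures. Genes named in the text follow a rule fixed before the data were examined. It takes all THADA probes, the 12 highest and 12 lowest genes with a RefSeq symbol, at or above the median signal and with all measured probes in one direction, and the 6 largest bounds each way. It also takes up to 4 genes per list with the largest differences, plus 1 in the opposite direction, and the text names some of these. Members named as measured on only 1 array were chosen after their values were seen. HOXB6 and APOE come from lists chosen after the main values were seen. Some genes that the rule takes are not reported here.

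The alternatives were normexp background correction (offset 50), quantile, median and loess scaling, the authors' processed values, the mean of a gene's probes, other filters on dim, outlier and saturated spots, other fold thresholds, unmatched random lists and list means. Scaling to the spike-in RNA was added after seeing the data. The 7 spike-in probes well above background on both arrays had a median unscaled log2 difference of 0.04 (range -0.02 to 0.11), and the probes for human transcripts had -0.47.

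The count of fold differences and the list comparison were tested on simulated gene values for this comparison with 16000 genes. For the folds, noise of 0.3 (SD, log2) was assumed. Background correction, scaling, probe choice and filters were not tested, and the noise holds no spread between cultures. The shares below are therefore not error rates of the 2 real arrays. Of 50 genes changed 4-fold, 100% passed 2-fold in the right direction, as did 82.0% of 50 changed 2.5-fold and 10.0% of 50 changed 1.5-fold. Of unchanged genes, 0.101% passed. Of 200 random lists of 15 genes, 7.00% fell outside the central 95%, and of 50 lists shifted by 1 log2 unit, 100% did. R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9, were used.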

Results

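Gene expression was measured in Huh7 cells, a line derived from a human hepatocellular carcinoma, on 2 one-colour Agilent microarrays. One array held RNA from cells labelled as carrying a short hairpin RNA (shRNA) against THADA, and the other held RNA from cells labelled as controls with a non-silencing shRNA. THADA is a large protein whose gene was first described at chromosomal breakpoints of thyroid adenomas. Both shRNAs were delivered by lentivirus packaged in HEK 293 cells, an embryonic kidney line, and the cells were kept under puromycin. Each group had 1 array, so no difference below has a replicate check, no test of the conditions was possible, and the errors given are technical. The free-text description of both arrays names a control siRNA, and the groups follow the treatment and source fields. Of 58717 spots for human transcripts, 46.9% were well above background on the knockdown array and 51.7% on the control array. The 75th percentile of signal was 206 and 341 units, respectively. No spot was saturated, and the small number of arrays limits the precision.

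The first question was whether THADA signal was lower on the array labelled knockdown. The probe A_23_P108376, spotted 10 times and matching NM_022065, gave 44.4 ± 6.49 units on that array and 243 ± 9.03 on the control array (SD over the 10 spots of each array). After scaling by the 75th percentile, the log2 difference was -1.74 (knockdown minus control, SD over spots 0.222), which was 3.35-fold lower. This probe lies on chromosome 2 at 43458445 to 43459873 (hg19, minus strand), and its sequence is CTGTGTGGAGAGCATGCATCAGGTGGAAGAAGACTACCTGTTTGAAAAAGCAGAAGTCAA. A second THADA probe, A_24_P101786 (chromosome 2, 43793891 to 43793950, minus strand), was not well above background on the knockdown array and was at least 1.5-fold lower there. Another probe, A_33_P3421611, matched a transcript described as a THADA fragment, and the files place it on the plus strand at 43460474 to 43460533. It had a log2 difference of -0.59, 1.51-fold lower, which was -0.30 with normexp and -1.35 under spike-in scaling. The THADA difference was larger than the spread between its spots, but 4.14% of the measured genes had a log2 difference as low or lower. With the normexp background correction, whose offset of 50 makes differences of dim probes smaller, the log2 difference of A_23_P108376 was -0.93. Among 13 measured genes beside THADA on the chromosome, the median log2 difference was 0.18 (44.4th percentile of random lists). OXER1 was 4.49-fold lower and KCNG3 was 2.46-fold higher.

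**Figure D1:**
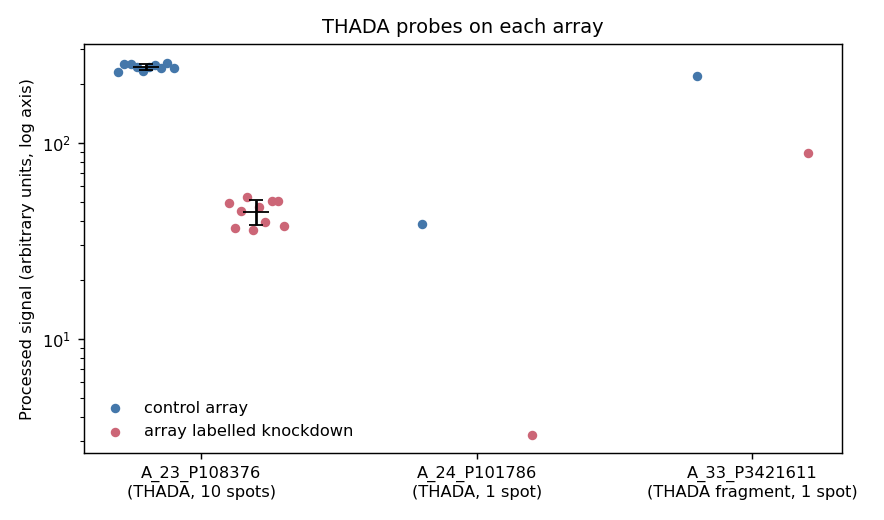
Processed signal (arbitrary units, log axis) of the 3 THADA probes on the control array (blue) and the array labelled knockdown (red), with 1 point per spot and, for the probe with 10 spots, the mean and SD over spots. The 10 spots of A_23_P108376 averaged 243 units on the control array and 44.4 on the knockdown array.

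The second question was how the transcriptomes on the arrays differed. Of 16000 genes well above background on both arrays, 2945 (18.4%) were at least 2-fold higher on the knockdown array and 1554 (9.71%) were at least 2-fold lower. The differences were uneven in size. Only 42 genes were at least 8-fold higher, against 202 at least 8-fold lower, and no gene was at least 100-fold higher, against 35 at least 100-fold lower. The median log2 difference of all measured genes was 0.27, so gene lists are set below against random lists matched on signal. Relative to that median, 1945 genes were at least 2-fold higher and 2221 at least 2-fold lower. Signals correlated across genes with r = 0.911, where genes are not independent replicates. For a single spot, the pooled SD of the log2 difference over 627 repeated probes was 0.131. Under scaling to spike-in RNA, chosen after seeing the data, the counts were 876 higher and 4464 lower.

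Among genes at or above the median signal, those lowest on the knockdown array included several plasma proteins. AGT, the angiotensin precursor, was 610-fold lower (80.4 against 80652 units, log2 difference -9.25, technical error 0.07). F2, which encodes prothrombin, was 609-fold lower, and AHSG, a plasma protein secreted by liver, was 539-fold lower. NTS, the neurotensin precursor, was 592-fold lower, the vitamin D carrier GC was 425-fold lower, and the asialoglycoprotein receptor subunit ASGR2 was 391-fold lower. The acute-phase proteins ORM2, HP, SERPINA1 and ORM1 were 377-, 353-, 349- and 316-fold lower, respectively. ALDH1A1, a retinaldehyde dehydrogenase, was 375-fold lower and APOC2, an apolipoprotein, 360-fold lower. Some genes were well above background on the control array only. APOH was at least 540-fold lower on the knockdown array, A2M at least 495-fold, PSPHP1 at least 366-fold, TM4SF5 at least 355-fold, TM4SF1 at least 339-fold and SCGN at least 279-fold. In all, 2226 genes were measured on the control array alone, and 857 of them had a bound of at least 2-fold.

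At or above the median signal, the genes highest on the knockdown array differed by far less. IFITM1, an interferon-induced membrane protein, was 19.3-fold higher (2830 against 242 units, log2 difference 4.27, technical error 0.21). The neurofilament subunits NEFL and NEFH were 12.3-fold and 8.23-fold higher. TNNT1, a troponin of slow skeletal muscle, was 9.90-fold higher and CPT1C, a brain carnitine palmitoyltransferase, 9.60-fold higher. INPP5D, an inositol phosphatase of blood cells, was 9.27-fold higher, HLA-DPA1 8.69-fold and HOXB2 8.57-fold. RBP7, HEY1, CD70 and HRK were between 7.75-fold and 8.38-fold higher. On the knockdown array alone, 656 genes were well above background, 522 of them with a bound of at least 2-fold. ASTN1 was at least 15.7-fold higher, VAV1 at least 14.4-fold, DMBX1 at least 13.8-fold, PNMT at least 12.9-fold, KIF17 at least 10.8-fold and FAM78B at least 10.3-fold.

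**Figure D2:**
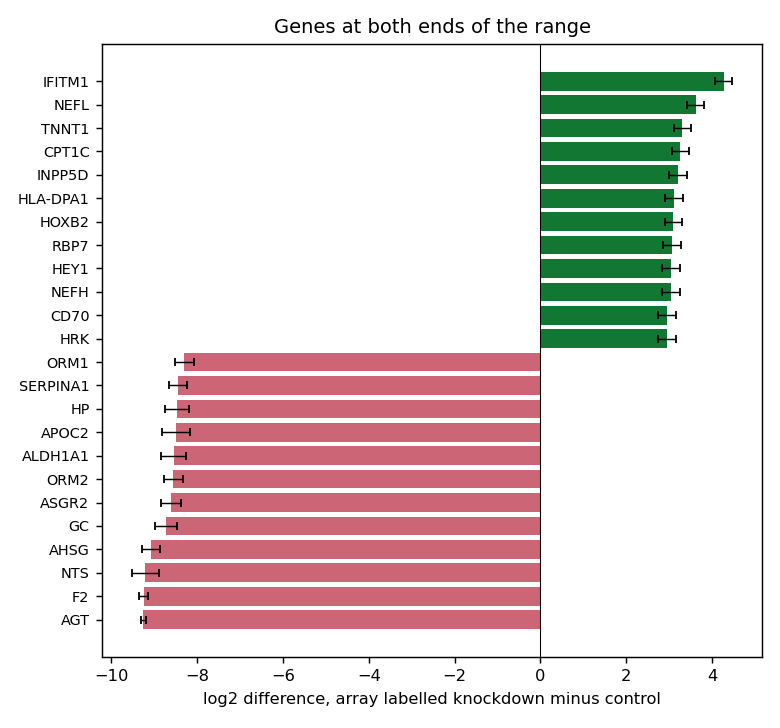
Log2 difference (array labelled knockdown minus control) of the 12 highest and 12 lowest genes chosen by a fixed rule among genes at or above the median signal, with the technical error from Agilent's error model as bars and 1 array per group. Among these genes AGT was lowest at -9.25 and IFITM1 highest at 4.27, and the dimmer NEFM, not drawn, was at 4.70.

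Of 42 gene lists fixed before the data were examined, 40 had at least 5 measured genes. The medians of 18 lists lay outside the central 95% of 10000 matched random lists, 14 below and 4 above. Were the genes of a list independent, 2 would be expected. Genes of a list can vary together and some lists share members, so these counts only describe the 2 arrays. The list of secreted hepatocyte proteins had a median log2 difference of -8.11, below all random lists, and 14 of its 15 measured genes were at least 2-fold lower. The exception was A1BG, with a log2 difference of 0.67, which was -0.090 under spike-in scaling. A further 9 members, among them APOB, FGA and SERPINC1, were measured on the control array only. Fetal liver and hepatoma genes had a median of -3.34, with 11 of 14 at least 2-fold lower. Among them were SPINK1 (276-fold), AFP, the alpha-fetoprotein gene (169-fold), and IGF2 (37.9-fold). Liver transcription factors had a median of -2.32, with 7 of 11 at least 2-fold lower. FOXA3 was 19.8-fold and FOXA2 9.75-fold lower, whereas NR2F1 had a log2 difference of 0.32, which was -0.44 under spike-in scaling. HNF4A was measured on the control array only. Beside these lower groups, all 9 measured embryonic kidney cell line markers were at least 2-fold higher on the knockdown array, with a median of 2.27. NEFM was 26.0-fold and PAX2 4.98-fold higher, and SIX2 and WT1 were measured on the knockdown array only.

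**Figure D3:**
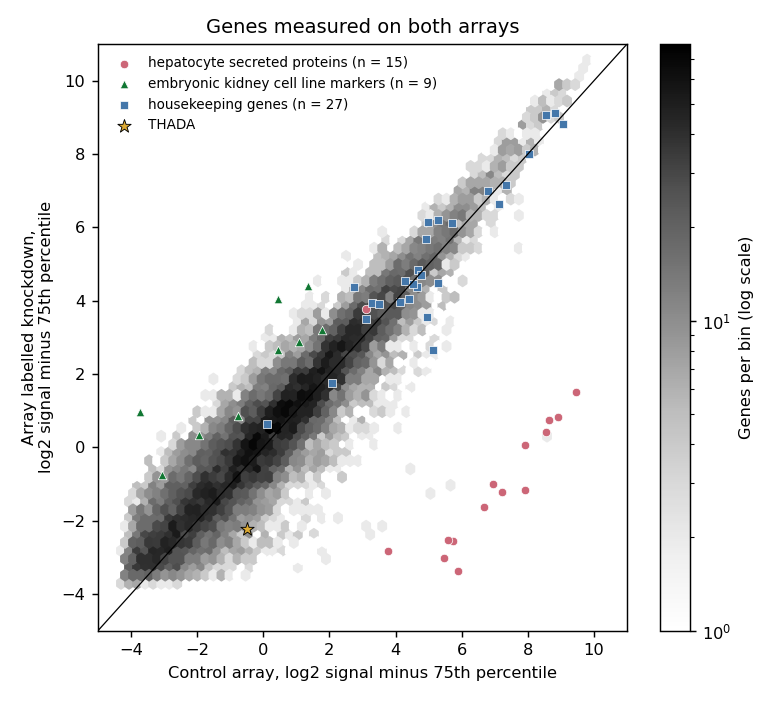
Signal of 16000 genes on the control array (x axis) and the array labelled knockdown (y axis), both log2 minus the array's 75th percentile, with grey bins for the number of genes and a line of equal signal. Secreted hepatocyte proteins (red) lie at a median of -8.11 relative to that line, embryonic kidney cell line markers (green) at 2.27 and housekeeping genes (blue) at 0.18.

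Lists of lipid synthesis and of drug and steroid metabolism lay below random lists. For cholesterol synthesis and uptake, 16 of 22 measured genes were at least 2-fold lower (median -1.67). HMGCS1, MSMO1 and IDI1 were 10.5-, 8.85- and 8.04-fold lower. For fatty acid and triglyceride synthesis, 13 of 20 were at least 2-fold lower (median -1.42). DGAT2, which makes triglycerides, was 20.9-fold lower and the desaturase gene FADS2 17.9-fold. SREBF1, a regulator of lipid synthesis, was 8.32-fold lower by its brightest probe, but its other measured probe went the opposite way. Drug and steroid metabolism had a median of -2.25, with 4 of 7 measured genes at least 2-fold lower. AKR1C1 was 79.5-fold and CYP3A7 54.2-fold lower, CYP1B1 was 3.37-fold higher, and 13 members were measured on the control array only. Among brighter genes only, fewer than 5 genes of that list were measured, so it was not compared with random lists there. Fatty acid oxidation genes had a median of -0.01 and lay within random lists, but outside them by the list mean. Even so, FABP1 was 271-fold lower and PDK4 was 4.61-fold higher. Only 3 bile acid genes were measured on both arrays, CYP27A1 at 63.2-fold lower, ABCB4 at 3.27-fold lower and SLC27A5 at 5.47-fold higher. Glycolysis genes had a median of 0.01 (7.27th percentile). HK2 was 6.26-fold lower, PFKP 6.17-fold higher and HK1 4.39-fold higher. The kidney line markers, at a median of 2.27, stood on the other side of these lipid groups.

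Inflammatory, complement and epithelial genes were lower as well. Of 11 measured NF-kB and inflammatory genes, 10 were at least 2-fold lower (median -2.47), with the chemokine genes CCL20 at 151-fold and CXCL1 at 24.9-fold lower. Complement and coagulation genes had a median of -3.05. The central complement component C3 was 251-fold lower, while C1R had a log2 difference of 0.89. Epithelial junction genes had a median of -1.67, with 11 of 16 at least 2-fold lower. EPCAM was 33.7-fold lower, the splicing regulator ESRP2 35.1-fold lower and KRT19 17.9-fold lower, while CLDN3 was 2.25-fold higher. Cholangiocyte markers, which share EPCAM and KRT19 with that list, had a median of -1.47 over 5 genes. Among brighter genes only, fewer than 5 of them were measured, so they were not compared with random lists there. Metallothionein and zinc genes had a median of -2.08, with 10 of 11 at least 2-fold lower and MT1G at 95.4-fold lower. Mesenchymal and matrix genes (median 0.66) lay within random lists, but outside them with the 2 looser background filters, and had members on both sides. TGFBI was 287-fold lower and TWIST1, a transcription factor of mesenchyme, was 4.66-fold higher. The same 9 kidney line markers were all at least 2-fold higher beside these groups.

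Of the stress groups, 3 lay below random lists and the others within them. Unfolded protein response genes had a median of -0.65, with 7 of 19 at least 2-fold lower, among them XBP1 at 3.45-fold lower. NRF2 targets had a median of -0.67, and the ferritin genes FTL and FTH1 were 9.17-fold and 3.87-fold lower. ER calcium handling genes, examined because THADA has been linked to calcium pumping at the endoplasmic reticulum, had a median of -0.25 (2.05th percentile). ATP2B1 was 3.17-fold lower and ORAI2 2.01-fold higher. This list lay within random lists under loess scaling, with each of the other background filters and by the list mean, and outside them in 10 of 15 settings. The ATF4 and amino acid response list had a median of 0.14, with PSPH at 13.7-fold lower and ATF3 at 3.20-fold higher. Heat shock genes had a median of 0.01 (outside random lists among brighter genes only), with HSPA1B at 4.18-fold higher and HSPE1 at 2.49-fold lower. Beside these stress groups too, the 9 kidney line markers were at least 2-fold higher.

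The groups higher on the knockdown array were the kidney line markers, p53 targets, ribosomal proteins and genes of G1/S and DNA replication. Of 20 p53 targets, 11 were at least 2-fold higher (median 1.12). The pro-apoptotic gene BBC3 was 3.73-fold, FDXR 3.52-fold and the cell cycle inhibitor CDKN1A 3.51-fold higher, while TP53I3 was 4.35-fold lower. Ribosomal protein genes had a median of 0.76 over 38 genes, with RPS3 at 2.23-fold and RPL38 at 2.17-fold higher. This list lay within random lists under quantile and loess scaling and for the authors' processed values, and its median was 0.0020 under spike-in scaling. G1/S genes had a median of 0.64, with POLA1 at 3.33-fold higher and FEN1 at a log2 difference of -0.34. The G1/S median was -0.12 under spike-in scaling, and the list lay within random lists with the mean of a gene's probes and when random lists were not matched on signal. Genes of G2/M and mitosis had a median of 0.15 and lay within random lists. Interferon-stimulated genes (median 0.63, 95.6th percentile, outside random lists among brighter genes only) went both ways. BST2 was 8.82-fold higher and ISG15 10.6-fold lower.

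**Figure D4:**
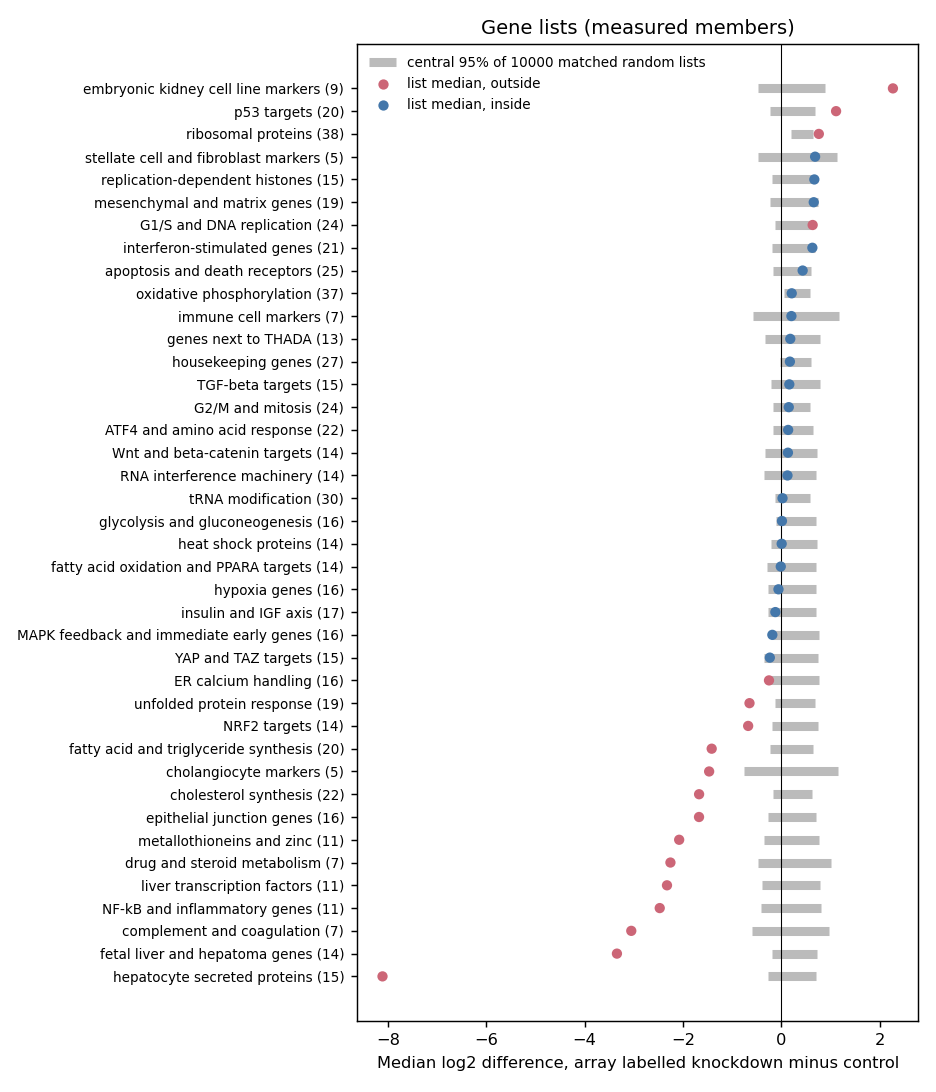
Median log2 difference (array labelled knockdown minus control) of the 40 gene lists with at least 5 measured genes (number in parentheses), with grey bars for the central 95% of 10000 signal-matched random lists. The secreted hepatocyte proteins lie lowest at -8.11 and the embryonic kidney cell line markers highest at 2.27.

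The remaining lists lay within random lists under the main settings, and their positive medians were negative under spike-in scaling. The median was -0.12 for the insulin and IGF axis, where GRB14 was 5.69-fold lower and SOCS2 4.08-fold higher, and -0.06 for hypoxia genes. It was 0.03 for tRNA modification, 0.44 for apoptosis and death receptors, 0.16 for TGF-beta targets, -0.23 for YAP and TAZ targets and 0.14 for Wnt targets. It was -0.18 for MAPK feedback genes, where DUSP6 was 23.2-fold lower and JUN 3.88-fold higher. The MAPK list lay outside random lists in 6 of 15 settings and the YAP and TAZ list in 2. It was 0.21 for oxidative phosphorylation, 0.67 for replication-dependent histones and 0.13 for the RNA interference machinery. Housekeeping genes had a median of 0.18, but TFRC was 5.59-fold lower and HPRT1 3.07-fold higher. Immune cell markers had a median of 0.21 (outside random lists by the list mean), and stellate cell and fibroblast markers 0.69. Of the endothelial markers, only CDH5 was measured on both arrays (2.46-fold higher).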

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

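Spike-in scaling was chosen after seeing the data, and the other settings before. Between 17 and 21 gene lists lay outside random lists under the 14 alternatives, and 13 of the 18 did so under all of them, including the hepatocyte, cholesterol, NF-kB, p53 and kidney line lists. The other 5 did so in 10 (ER calcium), 12 (ribosomal), 13 (G1/S) and 14 (drug metabolism and cholangiocyte) of 15 settings. For drug metabolism and cholangiocyte genes the remaining setting, brighter genes only, left fewer than 5 measured genes and made no comparison. Bile acid genes lay outside with the 2 looser background filters, which measured enough of them. Of 189 named genes, 177 kept their direction under every setting that measured them. The sizes were less stable. Of the values of named genes under the alternatives, 446 moved by at least the technical error of a single spot, 1747 did not and 16 changed sign. Of the "at least" bounds under other background correction or scaling, 48 values moved by at least the spread between repeated spots and 24 did not. The THADA log2 difference was -0.93 with normexp, -1.98 with loess and -2.51 with spike-in scaling, against -1.74. Genes at least 2-fold higher and lower numbered 2945 and 1554. With normexp 1839 were higher. With spike-in scaling 876 were higher and 4464 lower, so that 16.4% of the 2-fold differences were higher, against 65.5%, and 48.4% under loess scaling. Genes above background on at least 1 array gave 3139 lower, no filter gave 5847 higher and 3662 lower, and brighter genes alone gave 1183 and 744, as those filters take more or fewer genes. Thresholds of 1.5-, 3- and 4-fold gave 5506, 1197 and 550 higher and 2722, 806 and 507 lower. The spread between repeated spots was 0.302 over all repeated probes, dim ones included, against 0.131. Signs reversed for RPS12 (-0.16 under quantile scaling and for the authors' processed values, -0.29 under loess) and RGS5 (-0.25 under loess). Under spike-in scaling, which lowers every log2 difference alike, they reversed for A1BG (-0.090), NR2F1 (-0.44), DDIT4 (-0.28), UBE2C (-0.078), BIRC5 (-0.086), PLK1 (-0.11), RPS12 (-0.51), DROSHA (-0.052), AGO4 (-0.20), AIF1 (-0.075), DES (-0.074), RGS5 (-0.61) and, among lists outside random lists, the median of G1/S genes (-0.12). The positive medians of lists within random lists, such as housekeeping genes (-0.59) and genes beside THADA (-0.58), also turned negative there. The normexp offset of 50 is added to every signal, which makes differences of dim probes, THADA among them, smaller by construction. How much of the normexp changes came from the offset was not tested. Apart from those changes that a filter, a threshold, that common shift or the offset makes by construction, the cause was not tested. Keeping saturated probes moved nothing, as no spot was saturated. Signal over background limits the dim genes, among them THADA on the knockdown array at 44.4 units. F2 and HP gave 20.2 and 25.5 units there, where the lowest signal well above background was 15.4, so the sizes of such large folds are uncertain.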

Other observations

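The HOX, HLA, apolipoprotein and amino acid lists were chosen after the main values were seen. Of 27 measured HOX genes, 20 were at least 2-fold higher on the knockdown array and none at least 2-fold lower, with a median log2 difference of 1.36. HOXB2 was 8.57-fold and HOXB6 6.87-fold higher, HOXB3, HOXB7 and HOXB8 were measured there only, and HOXC10 and HOXD1 on the control array only. Of 16 genes of the HLA family and antigen presentation, 13 were at least 2-fold higher (median 1.63), while B2M, the light chain of class I molecules, was 2.65-fold lower. Apolipoprotein genes had a median of -4.50 over 6 measured genes, and APOB, which the hepatocyte list also holds, was measured on the control array only. Urea cycle and amino acid catabolism genes had a median of -0.98 over 8. Across the scalings tried, the medians stayed between 0.60 and 1.36 for HOX genes and between 0.87 and 1.63 for HLA genes. Lists for other cell types, written before their values were seen, had few genes measured on both arrays. Breast epithelial markers had a median of -1.67 over 7 genes, with ESR1, PGR and AGR2 measured on the control array only. Squamous, colon, melanocyte and leukaemia line lists had 4, 2, 3 and 4 such genes, and 5 further colon markers, among them VIL1 and CDH17, were measured on the control array only.

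Among the tests below, the second kidney list and the neighbouring-gene test were set before their results were seen, and all others after. The strongest pattern is that hepatocyte genes were lower and embryonic kidney line markers higher on the knockdown array. Abundant housekeeping genes did not fall with the hepatocyte genes, as their median lay only -0.094 log2 units from the median of all genes. This argues against degraded or poorly labelled RNA only where it would lower abundant messages in general. A loss shared by all genes would leave that value unchanged after scaling, so it was not excluded. Unscaled, probes for human transcripts had a median log2 difference of -0.47, against 0.04 for spike-in probes. RNA from another cell line, for which the HEK 293 packaging cells are a candidate source, could account for both sides, but of 14 measured genes in a second kidney line list 42.9% were at least 2-fold higher (median 0.85, 99.3rd percentile of random lists), between the bounds of 30% and 50% set beforehand. Of the first list, NEFH gave 4329 units on the knockdown array and 869 on the control array, NEFL gave 3425 and 461, and SIX2 and WT1 were measured on the knockdown array only, while whether puromycin would remove packaging cells was not tested. Loss of the hepatocyte programme within Huh7 cells after THADA silencing also stays open: 100% of the measured markers were at least 2-fold higher, but a change of programme could raise them too. The identity of the cells was not tested, and expression values from 1 array per group cannot tell these explanations apart.

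The hepatocyte messages left on the knockdown array were set against the idea of a small share of RNA like that of the control. Such a share would give 1 common ratio if the rest of the RNA held none of these messages. Over all 15 measured members of the secreted protein list, the SD of the log2 differences was 2.36, above the bound of 2 set for rejecting a common ratio, and the slope of knockdown on control log2 signal was 0.28. That failure rests on 1 gene, A1BG, which was higher on the knockdown array. A small share alone cannot account for A1BG, but the rest of the RNA could hold its message, so the failure does not exclude a small share. A repeat without A1BG, added only after the whole list had failed, gave an SD of 0.62 and a slope of 0.92 over the other 14 genes, but it decides nothing, because the gene was left out for its value. Neither run can decide whether a small share was present, and it stays open. Other liver messages had other ratios, such as IGF2 at 37.9-fold and APOE at 88.8-fold lower, and the same limit holds for them.

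The lower THADA signal could reflect silencing by the shRNA or a difference between 2 cell populations that has nothing to do with it. With 4.14% of measured genes as low or lower, THADA lay between the bounds of 1% and 5% set for either, and these cannot be told apart on 1 array per group.

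Log2 differences were also alike among genes far apart on the same autosome. Genes 20 to 50 measured genes apart had a mean rank correlation of 0.0794 over 15317 genes, above the highest of 1000 permutations (0.00470), as copy-number differences between the 2 cell populations would give. Medians of 16 of 22 autosomes lay outside the central 95% of permuted genes. The highest were on chromosomes 17, 19 and 22 (0.34, 0.31 and 0.29 above the median of all genes). The lowest were on chromosomes 9 and 7 (-0.36 and -0.30). This may mark 2 Huh7 clones or different lines, which the test does not separate. Regional differences in gene content and regulation could also exceed these permutations and were not tested, so the result does not single out copy number.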
